A study of Mus musculus with 4 samples.

How the data were processed

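RNA was counted in single cells of mouse cornea with 10x 3' v3.1 libraries, 2 from wild-type (WT) mice and 2 from Dot1l knockout (Dot1l-KO) mice. Per the labels, eyes of 10 mice of each genotype were used. The corneal epithelium was peeled off after Dispase II and dissociated with trypsin, the remaining stroma was digested with collagenase A, and the suspensions were pooled within each genotype. The labels do not say whether the libraries of a genotype came from separate pools, nor in what proportion epithelial and stromal suspensions were mixed. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalisation. Per the submitters' processing notes they were made with Cell Ranger 7.1.0 on build mm10, and Seurat 4.4.0 was used downstream. The annotation release is not stated. Of 32285 genes in the files, 32158 were matched by identifier in GENCODE M21, from which positions were taken. Symbols that occur more than once were told apart by identifier.

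A barcode was kept with at least 500 genes, at least 1000 UMIs and under 20% mitochondrial UMIs. Doublets were scored in each library with a Scrublet-style simulation (2 simulated doublets per cell) and an automatic threshold. Had this threshold marked under 0.5% or over 30% of barcodes, the top 0.8% per 1000 barcodes would have been removed instead, which was not needed. It removed 11.1% and 4.43% of barcodes in WT replicates 1 and 2, and 6.07% and 3.59% in Dot1l-KO replicates 1 and 2. Counts were log-normalised, and 2000 variable genes chosen within libraries gave 30 principal components. A graph of 20 neighbours, with a shared-neighbour Jaccard index of at least 0.0667, was clustered by Leiden at resolution 1 with seed 1 and no integration across libraries.

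Clusters were named from marker gene lists, by the mean log2 excess of the markers over the other clusters (pseudocount 20 CPM). A cluster with a score over 1.5 for a stromal, immune, vascular or other cell type took that name, and was epithelial-like otherwise. Among epithelial-like clusters, those with a cycling score over 1.5 were cycling, and the rest took the class with the highest score relative to the mean of these clusters. Here basal-like counted the higher of the basal and limbal scores, suprabasal-like the higher of the suprabasal and epidermal scores, and conjunctival-like the conjunctival score. Cluster 12 was thus basal-like by its limbal score (1.03), above its conjunctival (0.879) and basal (0.331) scores. An epithelial-like cluster whose 10 leading genes held more markers of another of these classes was called mixed and entered none of them. This befell only a cluster of 3122 Dot1l-KO cells under library-centred clustering. A cluster was left unnamed when fewer than 3 of its markers were detected in 10% of the cells, when its 10 leading genes held more markers of another class, when its UMI count was over 3 times below the library median with no marker among these genes, or when it was over 3 times above it. The marker lists were set before the data were examined, as were the comparisons, tests, filters and most alternatives. The rule that turns scores into names was set afterwards. Names carry the ending "-like", since they rest on RNA alone. Basal-like cells were clusters 3, 5, 6, 9, 12, 18 and 23, and suprabasal-like cells were clusters 0, 2, 4, 8, 10, 11, 13, 15 and 19. Conjunctival-like cells were clusters 7, 20 and 21, and cycling epithelial-like cells were clusters 14, 16 and 17. Together these form the epithelial-like cells. Stromal-like cells were clusters 1, 22 and 28, immune-like cells 24 and 27, and vascular-like cells 29. Clusters 25, 26, 30 and 31 were left unnamed. Most epithelial clusters held mainly cells of a single genotype. No cell atlas was used.

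For each class with at least 30 cells in each library, UMI counts were summed per library. Sums were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test, 2 libraries against 2) and Benjamini-Hochberg adjustment at 0.05. Vascular-like cells were too few in WT replicate 1 and Dot1l-KO replicate 1 to be tested. Levels are CPM on TMM-scaled library sizes, and folds are those fitted by edgeR. Where a genotype held 0 UMIs of a gene, the fold is a lower bound against a floor of 3 counts over the group. Where it held 1 to 3, the ratio is given with its 95% counting interval. Differences between basal-like and suprabasal-like changes were tested with a genotype by class term and library as a block. In epithelial-like cells 31 gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Sex-linked and erythrocyte genes were counted but not tested as lists, and the other lists are those whose results follow.

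The named genes were Dot1l in every comparison, and Krt12, Pax6, Krt5, Krt14, Krt15, Trp63, Krt4, Krt13, Krt10 and Krt6a in epithelial ones. Added to these were the 10 genes with the largest rise and the 10 with the largest fall in epithelial-like cells (5 and 5 in other classes). They needed an adjusted p under 0.05, no overlap between the genotypes and at least 20 CPM in the higher genotype, leaving out gene models, mitochondrial, ribosomal, haemoglobin and sex-linked genes. Up to 4 members of each list with the largest change past the threshold were named as well. Other genes in the text are members of a fixed list.

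Shares of cells are given with exact Clopper-Pearson intervals at 95%, which cover counting error only, and were compared by an exact two-sided permutation test. With 2 libraries against 2 the smallest possible p is 0.333. Shares of cells with a UMI of a gene were taken after thinning every cell to 1500 UMIs, leaving out shallower cells, and also unthinned.

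Alternatives planned for the fits were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, at least 10 CPM in 2 libraries, each library left out, and replicate number as a block. Others were doublets kept, under 10% mitochondrial UMIs, at least 1000 genes and 2000 UMIs, classes from resolution 0.5 or from library-centred clustering, and equal cells thinned to 1500 UMIs. A 2-fold minimum was applied to the counts, and shares with a UMI were also thinned to 3000 UMIs. After the data were examined, further alternatives were added: library totals with no scaling factors, and fry in either direction. Genes over 3 times higher in epithelial-like cells were also left out of the stromal-like and immune-like counts, and cluster 12 out of the basal-like cells, also in the test against suprabasal-like cells. The comparisons of conjunctival-like and of cycling epithelial-like cells were added at the same time.

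The fits were tested on simulated counts, drawn for each gene from the mean, dispersion and library sizes of the real sums. Far fewer genes were changed, by known folds, than were called in the data. In epithelial-like cells 23.9% of 1.5-fold, 71.4% of 2-fold and 93.7% of 4-fold changes were recovered, with 17.8% false calls among all calls. In all, basal-like, suprabasal-like, stromal-like and immune-like cells false calls made up 5.7% to 10.3% of calls. Conjunctival-like and cycling cells were not simulated. In immune-like cells 1.6%, 12.5% and 74.6% of the same changes were recovered. Of the simulated lists, 10 of 10 changed and 0 of 30 unchanged ones were called. Their members were drawn independently of each other, so this does not test lists whose genes move together.

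Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Raw reads were not analysed here.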

Results

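Single-cell RNA counts were collected from dissociated mouse corneas, 2 libraries from WT and 2 from Dot1l-KO mice. Dot1l encodes a histone methyltransferase. The WT libraries held 19085 and 11570 barcodes with 177403659 and 124061634 UMIs. The Dot1l-KO libraries held 16425 and 12021 barcodes with 180518730 and 151323715 UMIs. The median barcode had 7654, 9941, 8983 and 10638 UMIs in WT replicates 1 and 2 and Dot1l-KO replicates 1 and 2, in that order. After filters 16567, 10945, 14913 and 11248 cells were kept, of which 14327, 9144, 13834 and 10392 were epithelial-like. Summed epithelial-like counts of the WT libraries differed from each other beyond sampling noise, with a chi-square per degree of freedom of 47.2, and those of the Dot1l-KO libraries with 156. Because suspensions were pooled within each genotype, p-values measure a spread between libraries that may be technical.

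Dot1l itself was read first, as a check of the labels. Its raw level over all cells was 20.6 and 20.3 CPM in WT replicates 1 and 2, and 15.9 and 22.1 CPM in Dot1l-KO replicates 1 and 2. In epithelial-like cells it was 20.3, 19.45, 15.5 and 21.7 CPM from 2688, 2046, 2422 and 2981 UMIs, so that Dot1l-KO replicate 2 lay above both WT libraries. With TMM scaling Dot1l fell in epithelial-like cells from 22.8 ± 1.29 to 16.1 ± 2.83 CPM (SD, n = 2), a log2 change of -0.50 ± 0.15 (SE; edgeR adjusted p = 0.0335). This call ended without scaling factors (-0.10, adjusted p = 0.669), with at least 10 CPM in 2 libraries (-0.35, 0.127) and in cells thinned to 1500 UMIs (-0.40, 0.0512). It also ended without WT replicate 1 (-0.45, adjusted p = 0.124) and without Dot1l-KO replicate 1 (-0.33, 0.0796). Dot1l did not pass in all cells (log2 -0.39, adjusted p = 0.0862), in basal-like (-0.33, 0.181), stromal-like (-0.08, 0.850) or immune-like cells (-0.50, 0.683). In all cells it passed without Dot1l-KO replicate 2 (-0.55, adjusted p = 0.0179), and in stromal-like cells it turned to 0.04 without WT replicate 2, to 0.03 without Dot1l-KO replicate 2 and to 0.42 when thinned. In suprabasal-like cells it fell by 0.61 on the log2 scale (adjusted p = 0.0162). That call ended without WT replicate 1 (-0.62, adjusted p = 0.0547), without WT replicate 2 (-0.61, 0.0526), without scaling factors (-0.30) and with at least 10 CPM (-0.46). The gene (ENSMUSG00000061589) spans chromosome 10 from 80755206 to 80795461 on mm10. A 3' tag outside the deleted part checks nothing, and the labels do not say which part was deleted.

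The leading comparison asked how the corneal epithelium differs without Dot1l, which the series title links to its identity. In epithelial-like cells the corneal keratin gene Krt12 fell from 23418 ± 3460 to 5678 ± 263 CPM (SD, n = 2), 4.12-fold lower (log2 -2.04 ± 0.17 SE, edgeR adjusted p = 1.56e-04). Pax6, a transcription factor that specifies eye tissues, fell from 342 ± 7.18 to 158 ± 22.04 CPM (SD, n = 2), 2.17-fold lower (adjusted p = 0.00102). The genes of 3 proteins of the ocular surface fell with them: Lypd2 from 10622 ± 125.5 to 1113 ± 98.4 CPM (9.55-fold lower), its relative Slurp1 from 6216 ± 487 to 726 ± 50.2 CPM (8.56-fold lower) and the water channel gene Aqp5 from 10197 ± 981 to 2100.2 ± 316 CPM (4.86-fold lower; SD, n = 2). Krt14, a keratin gene of basal and epidermal keratinocytes, rose from 910.1 ± 41.6 to 4405 ± 1801 CPM (SD, n = 2), 4.84-fold higher (log2 2.28 ± 0.27 SE, adjusted p = 6.99e-04). Its partner Krt5 fell from 8658 ± 166 to 4289 ± 701 CPM (SD, n = 2; 2.02-fold lower, adjusted p = 0.002545), and Krt15, a keratin of limbal and basal cells, from 5903 ± 538 to 2595 ± 59.6 CPM (SD, n = 2; 2.27-fold lower, adjusted p = 8.11e-04). In each of these genes both Dot1l-KO libraries lay on the same side of both WT libraries.

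Keratins and regulators without a call in epithelial-like cells were the p53 relative Trp63, which maintains stratified epithelia (log2 -0.25, edgeR adjusted p = 0.241), the mucosal keratin genes Krt4 (-0.16, 0.435) and Krt13 (-0.38, 0.0807), the epidermal Krt10 (0.33, 0.127) and the wound keratin gene Krt6a (-0.41, 0.0699). Without scaling factors Trp63, Krt4 and Krt13 turned to 0.15, 0.23 and 0.01, and Krt10 passed at 0.74. Leaving out Dot1l-KO replicate 1 made Krt13 (-0.49, adjusted p = 0.0178), Krt10 (0.54, 0.001955) and Krt6a (-0.55, 0.00966) pass. The DESeq2 Wald test called Krt13 (0.0318) and Krt6a (0.0219), thinning called Krt6a (0.0126), and a minimum of 10 CPM called Krt10 (0.04995). On mm10, Krt12 (ENSMUSG00000020912), Krt14 (ENSMUSG00000045545) and Krt15 (ENSMUSG00000054146) lie on chromosome 11, from 99415666 to 99422259, 100203162 to 100207548 and 100131758 to 100135928. Pax6 (ENSMUSG00000027168) spans 105668900 to 105697364 on chromosome 2, and Krt5 (ENSMUSG00000061527) 101707070 to 101712898 on chromosome 15.

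**Figure D1:**
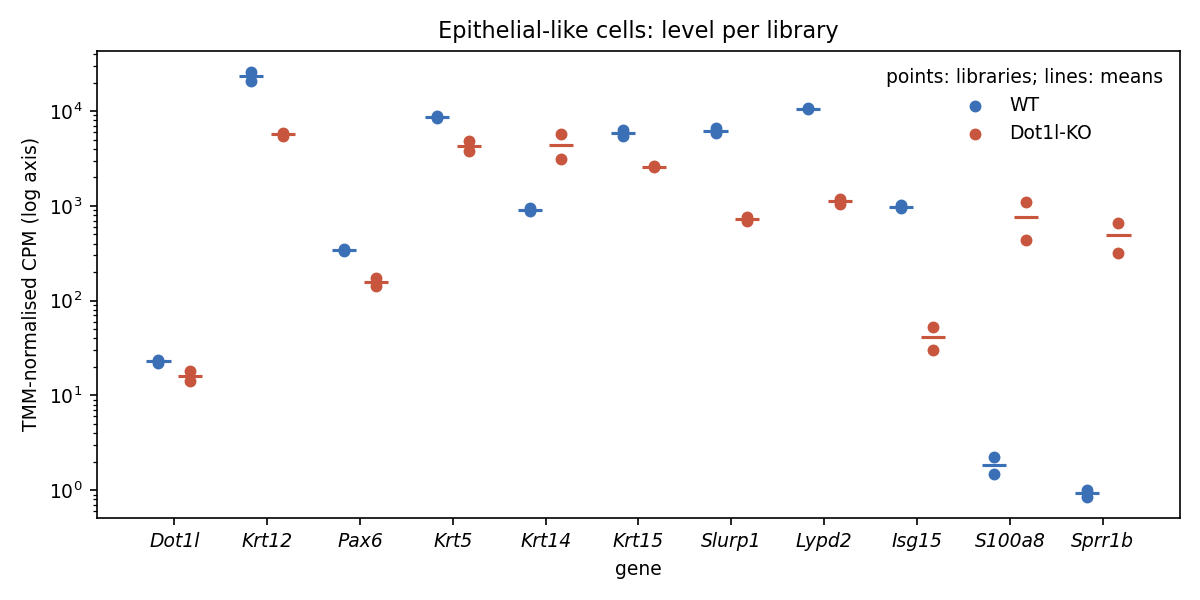
TMM-scaled CPM on a log axis for 11 genes in epithelial-like cells, with 1 point per library and a line at the mean of each genotype. Krt12 and Pax6 were lower in both Dot1l-KO libraries and Krt14 was higher.

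Genes of cornifying skin and alarmin genes were among the largest rises in the Dot1l-KO epithelium. Sprr1b, an envelope protein gene of cornified cells, rose from 0.932 ± 0.106 to 491 ± 239.6 CPM (SD, n = 2; 524-fold higher, log2 9.03, edgeR adjusted p = 2.90e-05). The keratinocyte differentiation gene Krtdap rose from 0.455 ± 0.205 to 144 ± 3.00 CPM (309-fold higher) and the epidermal secreted protein gene Dmkn from 4.27 ± 0.132 to 602 ± 338 CPM (141-fold). S100a8, an alarmin of neutrophils and stressed keratinocytes, rose from 1.85 ± 0.538 to 766 ± 463 CPM (SD, n = 2; 417-fold), and the fatty acid carrier gene Fabp4 from 0.755 ± 0.219 to 147 ± 40.8 CPM (192-fold). The platelet and epithelial chemokine gene Ppbp rose from 2.02 ± 1.01 to 322 ± 294 CPM (161-fold). The cornified envelope genes Sprr3 and Sprr2d and the milk casein gene Csn1s1 were close to 0 in WT and reached 46.8 ± 0.0933 CPM, 213 ± 242 CPM and 28.8 ± 10.9 CPM in Dot1l-KO (SD, n = 2). Csn1s1 had 2 UMIs in WT and 9737 in Dot1l-KO, a ratio of 2993 (counting interval 828 to 24720), and Sprr2e had 3 and 6988 (1432, 490 to 6945). Sprr2d and Sprr2e are close paralogs, so their counts may be shared. Of these genes Sprr1b, Sprr2d, Krtdap, Dmkn, S100a8 and Ppbp were among the 10 leading genes of the suprabasal-like cluster 10, which held 1 WT cell and 1812 and 680 cells of Dot1l-KO replicates 1 and 2, so these levels are means over unlike cells. Dot1l-KO replicate 1 carried the higher levels: without it the log2 change was 8.09 in place of 10.43 for Sprr2d, 8.75 in place of 10.38 for Sprr2e, 5.85 in place of 7.33 for Ppbp, 7.91 in place of 8.70 for S100a8, 6.42 in place of 7.14 for Dmkn and 8.43 for Sprr1b. Leaving out Dot1l-KO replicate 2 moved Sprr2d to 11.27, Sprr2e to 11.11 and Ppbp to 8.05. Without WT replicate 1 Csn1s1 moved from 11.41 to 15.01 and Sprr2d to 11.93, and without WT replicate 2 Csn1s1 moved to 10.595, Sprr2d to 9.79 and Ppbp to 7.94. Csn1s1 had only 2 WT UMIs in all, so its fitted values without a WT library are not exact folds. Thinning lowered Sprr3 from 10.87 to 9.40, Sprr2e to 8.14, Sprr1b to 8.12, S100a8 to 7.98 and Krtdap from 8.27 to 7.60, and with doublets kept Sprr2e was 9.53.

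Genes of the interferon response and of antigen presentation were among those lower in the Dot1l-KO epithelium. Isg15, a ubiquitin-like interferon-induced gene, fell from 984 ± 45.3 to 41.3 ± 15.8 CPM (SD, n = 2; 23.8-fold lower, log2 -4.57, edgeR adjusted p = 5.39e-05). Ifit1, which binds viral RNA, fell from 213 ± 8.74 to 19.4 ± 3.53 CPM (10.99-fold lower), and the RNA sensor gene Oas2 from 30.9 ± 4.11 to 2.60 ± 0.538 CPM (11.9-fold lower). B2m, the light chain of class I antigen-presenting molecules, fell from 550.1 ± 41.1 to 155 ± 30.1 CPM (SD, n = 2; 3.55-fold lower), and the immunoproteasome gene Psmb8 from 437 ± 39.6 to 133 ± 33.8 CPM (3.30-fold lower). Cyp4a12b, a fatty acid hydroxylase gene, fell from 216 ± 10.9 to 12.03 ± 0.107 CPM (SD, n = 2; 18.0-fold lower), and Ppp1r3c, a glycogen regulator, from 27.4 ± 2.45 to 2.43 ± 0.900 CPM (11.3-fold lower). The other members of the 10 largest falls were Igtp (15.5-fold lower), Apol9a (14.1-fold), Apol9b (10.9-fold), AC168977.2 (11.75-fold) and Ifi44 (10.4-fold). Igtp overlaps Irgm2 on the same strand, and Apol9a and Apol9b are paralogs, so their counts may be shared.

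Fixed gene lists were counted in epithelial-like cells, with counts adjusted over the list alone in parentheses. Of the corneal identity list, 2 rose and 14 fell of 19 (2 and 14), including the aldehyde dehydrogenase gene Aldh3a1 from 4461 ± 1081 to 1391 ± 194 CPM (3.21-fold lower; SD, n = 2). Of the epidermal keratinization list, 20 rose and 3 fell of 28 (21 and 4). Of the interferon response list, 1 rose and 24 fell of 26 (1 and 24), and of antigen presentation, 0 rose and 15 fell of 18 (1 and 16). Among basal progenitor genes 7 rose and 3 fell of 18 (8 and 3), with the hemidesmosome integrin Itgb4 up from 24.8 ± 0.599 to 52.5 ± 2.75 CPM (2.12-fold), and among limbal progenitor genes 5 rose and 4 fell of 13 (5 and 4). Of conjunctival genes 6 rose and 2 fell of 16 (6 and 3), of wound keratins 5 rose and 1 fell of 8 (5 and 2) and of mucins and glycocalyx genes 3 rose and 7 fell of 12 (3 and 7). Upk1b, a surface plaque protein gene, fell from 1139 ± 31.8 to 297 ± 6.09 CPM (3.83-fold lower). Of junction genes 5 rose and 13 fell of 30 (5 and 14), the desmosomal cadherin gene Dsg1a from 295 ± 1.64 to 76.5 ± 9.91 CPM (3.86-fold lower).

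Cell cycle, inflammatory and mesenchymal lists held more rises than falls in the epithelium, though by camera with an estimated correlation 0 of them passed, 0 also at an unadjusted p under 0.05. Cycling epithelial-like cells made up 7.08% ± 0.886 of WT and 13.7% ± 1.02 of Dot1l-KO epithelial-like cells (SD, n = 2; exact permutation p = 0.333), so that their share and expression mix in these counts. Of S phase genes 25 rose and 1 fell of 41 (26 and 1), again with counts adjusted over the list alone in parentheses, and of G2 and M phase genes 40 rose and 1 fell of 52 (44 and 2), with the cyclin-dependent kinase gene Cdk1 at 18.7 ± 2.06 to 38.2 ± 9.28 CPM (2.04-fold higher; SD, n = 2). Of inflammatory genes 15 rose and 2 fell of 27 (16 and 3), with the prostaglandin synthase gene Ptgs2 at 4.81 ± 0.579 to 43.5 ± 8.68 CPM (9.03-fold) and the chemokine gene Cxcl14 at 1.01 ± 0.342 to 14.4 ± 1.45 CPM (14.1-fold). Of antimicrobial and alarmin genes 10 rose and 3 fell of 14 (10 and 3). Of mesenchymal genes 14 rose and 3 fell of 20 (14 and 3), with the growth factor gene Tgfb2 at 1.68 ± 0.00227 to 17.7 ± 0.653 CPM (10.5-fold) and the calcium binding S100a4 at 13.6 ± 0.639 to 90.8 ± 3.12 CPM (6.66-fold). Of stromal matrix genes 7 rose and 13 fell of 24 (7 and 13) and of angiogenesis factors 6 rose and 3 fell of 17 (7 and 3). Stromal-like cells were a smaller share of Dot1l-KO (4.50%) than of WT cells (12.8%). Free stromal RNA was not tested as a source of the matrix falls. Of p53 targets 6 rose and 6 fell of 22 (6 and 6), the cell cycle inhibitor gene Cdkn1a falling 2.05-fold and the death gene Pmaip1 rising 5.17-fold, and of apoptosis genes 5 rose and 8 fell of 21 (5 and 8).

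Metabolic lists in the epithelium moved both ways. Of glycolysis genes 11 rose and 1 fell of 19 (14 and 1), with counts adjusted over the list alone in parentheses, the phosphofructokinase gene Pfkp from 8.04 ± 1.53 to 25.8 ± 1.79 CPM (3.21-fold higher; SD, n = 2). Of cholesterol synthesis genes 1 rose and 12 fell of 19 (1 and 13), the sterol sensor partner gene Insig1 from 206 ± 19.8 to 79.4 ± 6.74 CPM (2.59-fold lower). Of oxidative phosphorylation genes 1 rose and 4 fell of 28 (0 and 3), and of oxidative stress genes 10 rose and 6 fell of 26 (10 and 6), the glutathione transferase gene Gsta4 from 10422 ± 1498 to 2601 ± 941 CPM (4.01-fold lower) and the peroxidase gene Gpx2 from 3.61 ± 0.846 to 29.9 ± 2.07 CPM (8.31-fold higher). Of heat shock genes 4 rose and 7 fell of 22 (5 and 7) and of immediate early genes 4 rose and 11 fell of 20 (4 and 11), the transcription factor gene Fos from 1057 ± 87.8 to 546 ± 124 CPM (1.94-fold lower). Of DOT1L partners 4 rose and 2 fell of 18 (4 and 2), of Notch genes 3 rose and 2 fell of 14 (3 and 2), of Wnt genes 4 rose and 2 fell of 21 (4 and 2) and of histone and chromatin genes 4 rose and 2 fell of 24 (4 and 2). Of sex-linked genes 0 rose and 2 fell of 5 (0 and 2), calls that ended without scaling factors and without WT replicate 1. Of erythrocyte genes 0 rose and 1 fell of 3 (0 and 1), of ribosomal protein genes 2 rose and 0 fell of 85 (0 and 0) and of mitochondrially encoded genes 4 rose and 0 fell of 13 (4 and 0).

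**Figure D2:**
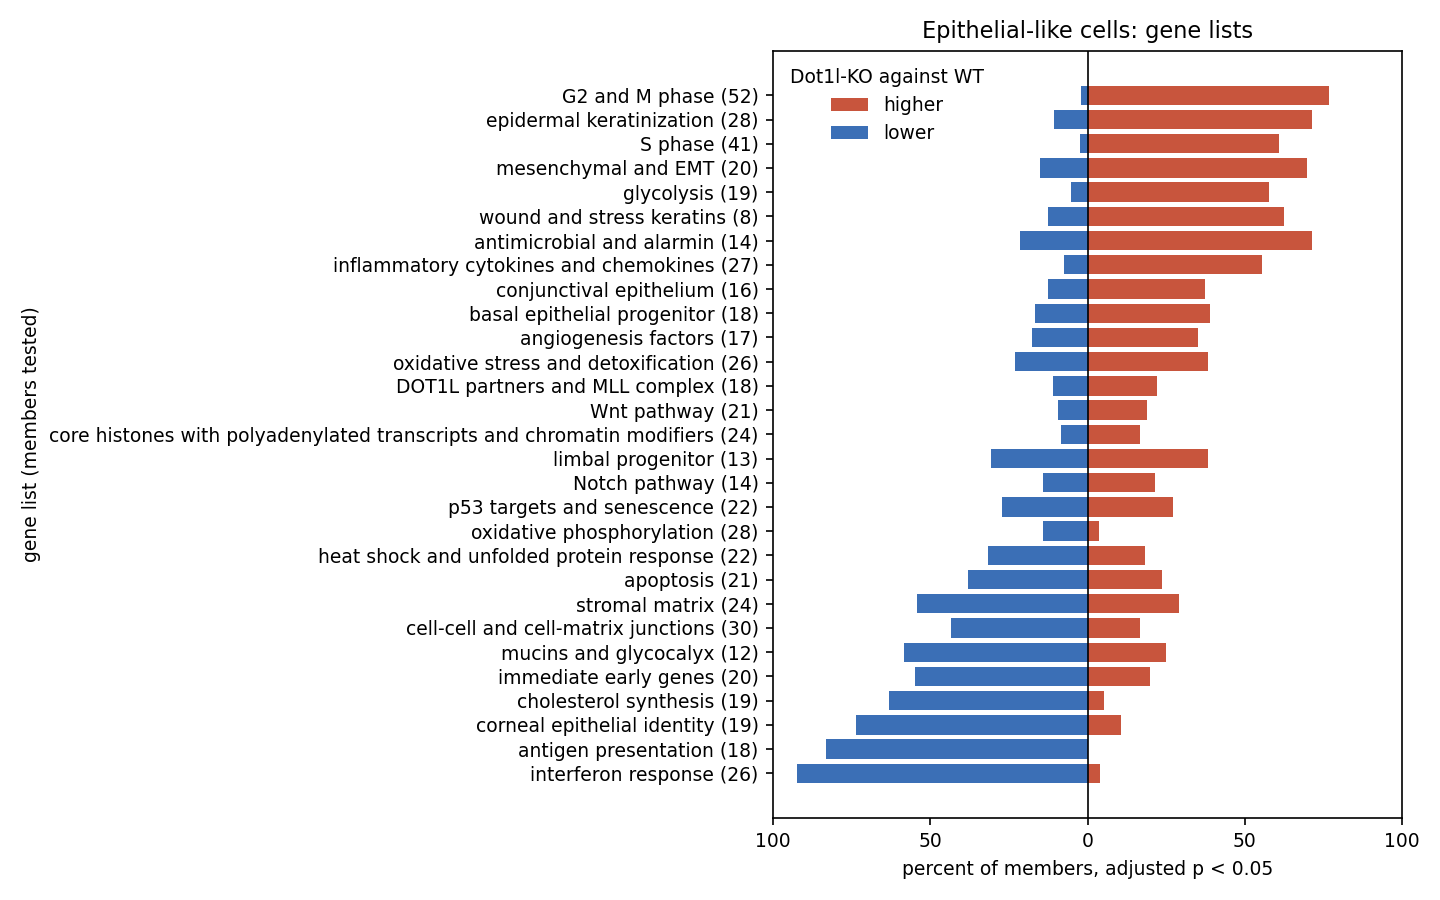
Percent of the tested members past the threshold in epithelial-like cells, higher (right) or lower (left) in Dot1l-KO than in WT, for gene lists of under 60 tested members with at least 5 past it. Interferon response genes were nearly all lower, with 24 of 26, and G2 and M phase genes were mostly higher, with 40 of 52.

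Across epithelial-like cells edgeR called 7234 of 18128 genes, 3947 higher and 3287 lower in Dot1l-KO. Of these 3595 changed at least 2-fold, 2574 of them higher. The genotypes did not overlap in 72.4% of tested genes, where chance gives 33.3%. The top 10 genes took 16.2% and 16.25% of the UMIs in WT and 10.2% and 10.1% in Dot1l-KO. Without scaling factors the median log2 change of all tested genes moved to 0.41 and 8655 genes passed, 7395 higher and 1260 lower. By limma camera 14 of the 31 lists tested passed. Those higher were epidermal keratinization (adjusted p = 4.42e-05), S phase (8.94e-05), G2 and M phase (1.13e-06), inflammatory (0.00105), antimicrobial (0.0162), glycolysis (0.0145) and mesenchymal genes (0.00965). Those lower were corneal identity (2.72e-04), interferon response (7.41e-14), antigen presentation (1.97e-06), cholesterol synthesis (8.94e-05), junctions (0.0228), immediate early (0.0248) and stromal matrix genes (0.0192). The stromal matrix list shares Aldh3a1 and Tkt with the corneal identity list. Stromal-like cells were 12.8% of WT and 4.50% of Dot1l-KO cells, and free stromal RNA was not tested as a source of its fall. With an estimated correlation camera called 0 lists, 0 of them at an unadjusted p under 0.05, the adjusted p being 0.644 for most, 0.731 for antimicrobial and glycolysis genes and 0.773 for S phase genes, while fry called 11 lists moving on balance one way. Median, mean and tests differed in sign for apoptosis (median 2.30e-04, mean 0.42, lower by camera), DOT1L partners (median -0.08, mean 0.05, lower by camera), chromatin genes (median -0.03, mean 0.01, lower by camera) and ribosomal proteins (median 0.03, mean 0.04, lower by camera), each higher by fry. None of these 4 passed camera.

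Basal-like cells were compared to ask whether the change reaches the basal layer (clusters 3, 18 and 23 of mostly WT cells, 5, 6 and 9 of mostly Dot1l-KO cells, and 12). The clusters named cycling (14, 16 and 17) are not among them, but single cycling cells were not removed from the basal-like clusters. Cycling scores were -0.862, -0.309 and -1.01 in clusters 5, 6 and 9, and -1.08, -0.993 and -1.21 in clusters 3, 18 and 23. The share of cycling cells and expression may thus mix in the cell cycle genes called here. Krt12 fell from 10540 ± 2887 to 3835 ± 165 CPM (SD, n = 2; 2.75-fold lower, edgeR adjusted p = 7.36e-04), Pax6 from 356 ± 3.42 to 181 ± 28.2 CPM (1.97-fold lower) and Krt15 from 7819 ± 592 to 2414 ± 247 CPM (3.24-fold lower). Krt14 rose from 2664 ± 18.7 to 4571.5 ± 1207 CPM (SD, n = 2; 1.72-fold, adjusted p = 0.0169), a call that ended without Dot1l-KO replicate 1 (log2 0.48 in place of 0.78, adjusted p = 0.147). Isg15 fell from 166 ± 7.43 to 15.1 ± 6.27 CPM (11.004-fold lower) and Ifit3, another interferon-induced gene, from 55.4 ± 0.602 to 6.36 ± 2.13 CPM (8.73-fold lower). The protease inhibitor gene Serpina3n rose from 1.01 ± 0.435 to 29.2 ± 6.48 CPM (29.1-fold), Ptgs2 from 10.2 ± 1.502 to 77.7 ± 17.5 CPM (7.60-fold) and the replication gene Uhrf1 from 10.0 ± 1.04 to 29.5 ± 7.91 CPM (2.95-fold). S100a8 rose 143-fold (log2 7.15, 6.24 without Dot1l-KO replicate 1, and between 6.20 and 7.77 under other classes, thinning and doublets kept, and 8.14 without cluster 12). Krt5 fell from 6658 ± 396 to 3977 ± 549 CPM (adjusted p = 0.0108), a call that ended without Dot1l-KO replicate 2 (log2 -0.61 in place of -0.74) and with doublets kept (-0.55). Krt4 (3.23-fold lower) and Krt13 (2.87-fold lower) were lower as well, but cluster 12, near the conjunctival-like class, held 2181 and 3888 CPM of them and made up 20.8% of WT and 8.22% of Dot1l-KO basal-like cells. Without it Krt4 went from 111.5 ± 44.55 to 40.45 ± 4.16 CPM (log2 -1.46, adjusted p = 0.00325) and Krt13 from 121 ± 25.8 to 60.8 ± 12.5 CPM (-0.99, 0.00868; SD, n = 2), the call of Krt5 ended (-0.53, 0.0711) and Krt15 stood at -0.90 (0.0110). Trp63 did not pass (log2 -0.26, adjusted p = 0.356). With classes from resolution 0.5, Krt12 moved from -1.46 to -2.35 and Krt15 from -1.70 to -0.73. There a basal-like cluster with 4257 and 2025 WT and 66 and 47 Dot1l-KO cells held 30981 CPM of Krt12. Library-centred clustering moved Krt15 to -2.60, Krt4 from -1.69 to -4.30 and Krt13 from -1.52 to -4.52, and with doublets kept Krt4 was -2.54. A basal-like cluster of the centred clustering had 899 and 501 WT and 5 and 2 Dot1l-KO cells. It held 17891 CPM of Krt15, 2128 of Krt4 and 3650.5 of Krt13. Class makeup and expression thus mix in the values from these 2 clusterings.

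In basal-like cells the other large rises were Fabp4 (52.4-fold; log2 5.71, 6.74 with doublets kept), Krtdap (44.5-fold) and Ppbp (37.4-fold; log2 5.23, 3.75 without Dot1l-KO replicate 1 5.94 without Dot1l-KO replicate 2 and 6.56 without cluster 12). Krtdap stood at 5.48 on the log2 scale, 6.57 with doublets kept, 6.93 without cluster 12 and 3.89 after library-centred clustering. Of S phase genes 27 rose and 0 fell of 41 (30 and 0), with counts adjusted over the list alone in parentheses, of G2 and M phase genes 32 rose and 0 fell of 52 (35 and 1) and of interferon response genes 1 rose and 23 fell of 26 (1 and 24). Of antigen presentation genes 0 rose and 15 fell of 17 (0 and 16), of corneal identity genes 2 rose and 14 fell of 18 (2 and 15) and of inflammatory genes 16 rose and 1 fell of 26 (16 and 3). Krt10 (log2 -0.56, edgeR adjusted p = 0.0258) and Krt6a (-0.66, 0.0305) fell, but without cluster 12 Krt10 did not pass (-0.43, 0.101) and Krt6a turned to a rise (0.77, 0.0329). The Krt10 call ended without WT replicate 1 (-0.49), without Dot1l-KO replicate 2 (-0.45), without scaling factors (-0.37) and with doublets kept (-0.45), and that of Krt6a without WT replicate 1 (-0.62), without Dot1l-KO replicate 2 (-0.42) and with doublets kept (0.39). In all, 3570 of 15394 genes passed, 2108 higher and 1462 lower, and 1949 changed at least 2-fold. Without cluster 12, 2456 passed, 1588 higher and 868 lower. No overlap between genotypes was seen in 61.7% of tested genes, with 33.3% by chance. With no scaling factors the median moved to 0.19, and 3810 genes passed, 2945 higher and 865 lower.

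Suprabasal-like cells were compared as the layer in which corneal keratins are normally highest (clusters 0, 2, 4, 11 and 15 of mostly WT cells, and 8, 10, 13 and 19 of mostly Dot1l-KO cells). Krt14 rose from 57.9 ± 0.295 to 5046 ± 2208 CPM (SD, n = 2), 87.2-fold higher (log2 6.45 ± 0.33 SE, edgeR adjusted p = 4.57e-06; log2 5.43 with doublets kept). Krt12 fell from 31135 ± 1371 to 9444 ± 481 CPM (SD, n = 2; 3.30-fold lower, adjusted p = 4.86e-05), and Pax6 (2.11-fold lower), Krt5 (1.85-fold lower) and Krt15 (2.06-fold lower) fell too. Krt4 rose from 152 ± 10.5 to 623 ± 49.9 CPM (4.10-fold) and Krt10 from 45.8 ± 2.79 to 94.8 ± 37.2 CPM (2.07-fold). Sprr1b rose from 0.546 ± 0.247 to 1037 ± 391 CPM. Il33, an alarmin cytokine, rose from 3.22 ± 0.0231 to 128 ± 61.9 CPM (39.7-fold; log2 5.31, 4.71 without Dot1l-KO replicate 1) and Pfkp rose 7.14-fold. Isg15 fell from 1259.9 ± 0.0113 to 56.8 ± 22.4 CPM (22.2-fold lower), Ddx60, an antiviral helicase gene, from 204 ± 7.45 to 14.2 ± 0.628 CPM (14.4-fold lower) and Cyp4a12b from 294 ± 35.5 to 19.8 ± 1.37 CPM (14.9-fold lower). After library-centred clustering Isg15 moved from -4.47 to -5.82, Ddx60 from -3.85 to -4.83 and Cyp4a12b from -3.89 to -4.54. Csn1s1 was at least 2202-fold higher, with 0 UMIs in WT, and Sprr3 had 3 UMIs in WT and 15544 in Dot1l-KO, a ratio of 4676 (1600 to 22680). The fitted log2 change of Sprr3 was 12.10, 15.82 without WT replicate 1 and 11.34 without WT replicate 2. With only 3 WT UMIs in all these are not exact folds.

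Trp63 fell by 0.42 on the log2 scale in suprabasal-like cells (edgeR adjusted p = 0.0352) and Krt13 rose by 0.41 (0.0481). Both calls ended without WT replicate 1 (log2 -0.54 and 0.29) and without WT replicate 2 (-0.32 and 0.51). They also ended with classes from resolution 0.5 (-0.12 and -0.07) and from library-centred clustering (-0.16 and -0.41). That of Trp63 further ended without scaling factors (-0.11), with at least 10 CPM (-0.27) and thinned (-0.39), and that of Krt13 with doublets kept (0.40, adjusted p = 0.06495). Under library-centred clustering a mixed cluster of 3122 Dot1l-KO cells, with 7437 CPM of Krt13, was not part of the suprabasal-like class. Krt6a did not pass (log2 0.03, 0.898). Of epidermal keratinization genes 24 rose and 3 fell of 28 (24 and 3), with counts adjusted over the list alone in parentheses, of conjunctival genes 9 rose and 1 fell of 14 (10 and 1) and of interferon response genes 1 rose and 24 fell of 25 (1 and 24). Of corneal identity genes 3 rose and 13 fell of 19 (4 and 14), of S phase genes 22 rose and 7 fell of 41 (22 and 7), of G2 and M phase genes 34 rose and 3 fell of 52 (38 and 3) and of ribosomal protein genes 26 rose and 0 fell of 84 (20 and 0). In all, 6724 of 15760 genes passed, 3801 higher and 2923 lower, and 3588 changed at least 2-fold. In 74.2% of tested genes the genotypes did not overlap, against 33.3% by chance. The median moved to 0.31 with no scaling factors, and 7240 genes passed, 5910 higher and 1330 lower. Between basal-like and suprabasal-like cells the change itself differed in 4239 of 16798 genes, with 2444 more positive and 1795 more negative in suprabasal-like cells. The changes of Krt12 (log2 difference -0.31, adjusted p = 0.158), Pax6 (-0.115, 0.408) and Dot1l (-0.30, 0.0918) did not differ past the threshold.

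**Figure D3:**
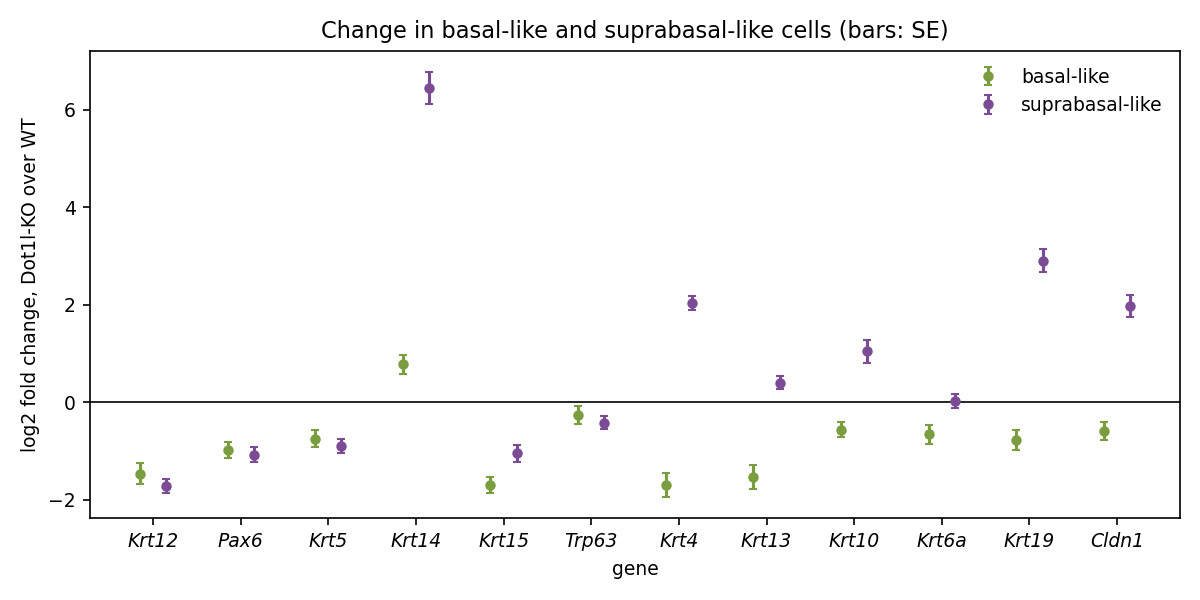
Log2 fold change of Dot1l-KO over WT for 12 genes in basal-like and suprabasal-like cells, as points with bars of 1 SE. Krt14 was at 6.45 in suprabasal-like cells and 0.78 in basal-like cells, and Krt4 was above 0 in the first and below 0 in the second, also without cluster 12, while without it Krt6a in basal-like cells turned to 0.77 and Krt19 to 0.40.

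Stromal-like cells were compared to see whether tissue under the epithelium differs too (clusters 1, 22 and 28, with 1897, 1542, 589 and 569 cells). Cluster 1 held 81.3% of the WT and 39.2% of the Dot1l-KO cells, and cluster 22, with Mmp3, Saa3 and Chil1 as its leading genes, 14.8% and 54.3%, so that the makeup of the class and expression mix. Saa3, an acute phase protein gene, rose from 3.37 ± 4.41 to 2471 ± 1236 CPM (SD, n = 2; 706-fold, log2 9.46 ± 0.57 SE, edgeR adjusted p = 6.20e-08). The iron trapping protein gene Lcn2 rose from 0.822 ± 0.802 to 183 ± 100.7 CPM (209.5-fold). Tnc, a matrix protein of wounds, rose from 45.1 ± 13.3 to 276 ± 60.5 CPM (6.11-fold; log2 2.61, 2.01 thinned), the smooth muscle actin gene Acta2 from 6.87 ± 0.380 to 24.4 ± 8.34 CPM (3.49-fold) and the matrix gene Fbln1 from 45.3 ± 0.6205 to 131 ± 15.2 CPM (2.89-fold). The neutrophil chemokine gene Cxcl5 rose from 30.2 ± 11.7 to 155 ± 38.5 CPM (5.18-fold). Saa2, with 0 UMIs in WT, was at least 217-fold higher, and the macrophage elastase gene Mmp12 had 1 UMI in WT and 867 in Dot1l-KO (ratio 2205, interval 395 to 87190). Saa1 and Saa2 are paralogs, so their counts may be shared. Isg15 fell from 37.5 ± 8.035 to 9.49 ± 0.705 CPM (3.96-fold lower), Ifit3 from 88.1 ± 5.97 to 34.2 ± 2.92 CPM (2.57-fold lower) and the growth factor receptor gene Kdr from 177 ± 14.3 to 79.0 ± 10.8 CPM (2.24-fold lower). The serotonin receptor gene Htr5b fell from 49.8 ± 0.0616 to 10.65 ± 1.58 CPM (4.71-fold lower). Without WT replicate 1 Saa3 stood at 8.56 on the log2 scale, without WT replicate 2 at 13.10, without Dot1l-KO replicate 1 at 8.84 and thinned at 8.32. Lcn2 moved from 7.71 to 7.01, 9.34, 7.02 and 6.07 in the same order. For Mmp12 the fitted 10.79 became 12.53 and 9.90 without WT replicates 1 and 2, and 8.97 and 11.65 without Dot1l-KO replicates 1 and 2. Mmp12 had only 1 WT UMI in all, so these are not exact folds.

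Of antimicrobial and alarmin genes in stromal-like cells 9 rose and 2 fell of 12 (9 and 2), with counts adjusted over the list alone in parentheses, and of inflammatory genes 8 rose and 0 fell of 23 (8 and 0). Of interferon response genes 0 rose and 10 fell of 24 (0 and 13), of immediate early genes 0 rose and 8 fell of 20 (0 and 14) and of ribosomal protein genes 0 rose and 14 fell of 83 (0 and 25). Of stromal matrix genes 7 rose and 3 fell of 23 (7 and 5) and of mesenchymal genes 5 rose and 1 fell of 19 (8 and 4). By edgeR 1053 of 12958 genes passed, 628 higher and 425 lower, and 476 changed at least 2-fold. Without WT replicate 1, 625 genes passed, and without Dot1l-KO replicate 2, 641 did. Of the tested genes 52.6% did not overlap between genotypes, with 33.3% by chance. Slurp1 (8.17-fold lower) and Lypd2 (6.35-fold lower), named among the falls, and Isg15 are over 3 times higher in epithelial-like cells. Such genes made up 174 of the calls, 110 higher and 64 lower, and without them 879 calls were left, 518 higher and 361 lower. Genes that rose in the epithelium rose here too, as Dmkn (0 UMIs in WT and 111 in Dot1l-KO) and Sprr1b (2 and 88). The list counts were not recomputed without such genes. The part of epithelial RNA in the rises of antimicrobial and alarmin genes was not tested. Without scaling factors the median moved to 0.10 and 1276 genes passed, 1000 higher and 276 lower.

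Immune-like cells were the smallest class tested (clusters 24 and 27, with 150, 80, 271 and 134 cells). The interferon regulator gene Irf7 fell from 182 ± 42.3 to 25.7 ± 8.94 CPM (SD, n = 2; 6.85-fold lower, edgeR adjusted p = 0.00538), a call that ended in thinned cells (log2 -2.96, adjusted p = 0.127). Aoah, which detoxifies bacterial lipid, fell from 95.5 ± 6.44 to 8.34 ± 2.98 CPM (11.7-fold lower), also not passing when thinned (0.204). Isg15 fell from 349 ± 0.260 to 57.1 ± 30.1 CPM (5.93-fold lower). S100a8 rose from 6.45 ± 9.13 to 839.6 ± 20.7 CPM (154-fold) and its partner gene S100a9 from 8.57 ± 6.14 to 1066 ± 212 CPM (134-fold), but with doublets kept neither passed (log2 1.45 and 2.14). Retnlg, a neutrophil secreted protein gene, was at least 13.6-fold higher against 0 UMIs in WT, and turned to -0.01 on the log2 scale with doublets kept. Genes that also rose in the epithelium passed here too, as Dmkn (0 UMIs in WT and 210 in Dot1l-KO) and Il33 (0 and 59). Clusters 24 and 27 held 3581 and 5442 CPM of the epithelial gene Krt12. The part of epithelial RNA in these rises, S100a8 and S100a9 among them, was not tested. Nor was it tested in the falls of interferon response genes, and Isg15 was higher in WT epithelial-like than in WT immune-like cells. Without WT replicate 1 S100a8 moved from 7.27 to 6.01 and S100a9 from 7.06 to 6.36, and without WT replicate 2 they moved to 12.305 and 7.91. S100a8 was seen in a single WT library of these cells, so 12.305 is not an exact fold. Isg15 moved from -2.57 to -3.26 without Dot1l-KO replicate 1 and did not pass when thinned (adjusted p = 0.0887). Of interferon response genes 0 rose and 8 fell of 23 (0 and 19), with counts adjusted over the list alone in parentheses, of inflammatory genes 1 rose and 3 fell of 22 (8 and 6) and of antimicrobial and alarmin genes 3 rose and 2 fell of 10 (6 and 3). In all, 86 of 7098 genes passed, 51 higher and 35 lower, 11 of them over 3 times higher in epithelial-like cells. Without WT replicate 1, 51 passed, and without Dot1l-KO replicates 1 and 2, 293 and 233 did. The genotypes did not overlap in 41.5% of tested genes against 33.3% by chance. Without scaling factors the median moved to 0.12 and 79 genes passed, 55 higher and 24 lower.

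Summed over all cells, where cell makeup and expression mix, 6114 of 19055 genes passed by edgeR, 3148 higher and 2966 lower. Isg15 fell from 878 ± 70.0 to 42.6 ± 16.9 CPM (SD, n = 2; 20.6-fold lower, adjusted p = 1.70e-04) and Lypd2 from 9459.8 ± 450.1 to 1132 ± 81.5 CPM (8.35-fold lower). The keratocyte gene Kera fell 5.52-fold. Of interferon response genes 1 rose and 25 fell of 26 (1 and 25), with counts adjusted over the list alone in parentheses, of corneal identity genes 2 rose and 12 fell of 19 (3 and 13) and of epidermal keratinization genes 20 rose and 3 fell of 28 (23 and 3). The genotypes did not overlap in 68.8% of tested genes against 33.3% by chance. Without scaling factors the median moved to 0.27 and 6807 genes passed, 5209 higher and 1598 lower.

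Shares of cell classes were compared to describe the makeup of the suspensions. Stromal-like cells made up 12.8% ± 1.87 of WT and 4.50% ± 0.784 of Dot1l-KO cells (SD, n = 2; 2.84-fold lower; exact two-sided permutation p = 0.333, the smallest possible). By library they were 11.45% (exact interval 10.97 to 11.95), 14.09% (13.44 to 14.75), 3.95% (3.64 to 4.28) and 5.06% (4.66 to 5.48). Epithelial-like cells made up 85.0% ± 2.08 of WT and 92.6% ± 0.265 of Dot1l-KO cells. These shares depend on how epithelial and stromal suspensions were combined, which the labels do not give. Immune-like cells made up 0.818% ± 0.123 and 1.504% ± 0.443, the Dot1l-KO libraries above both WT libraries, and vascular-like cells 0.249% ± 0.139 and 0.218% ± 0.0811 (exact permutation p = 1).

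**Figure D4:**
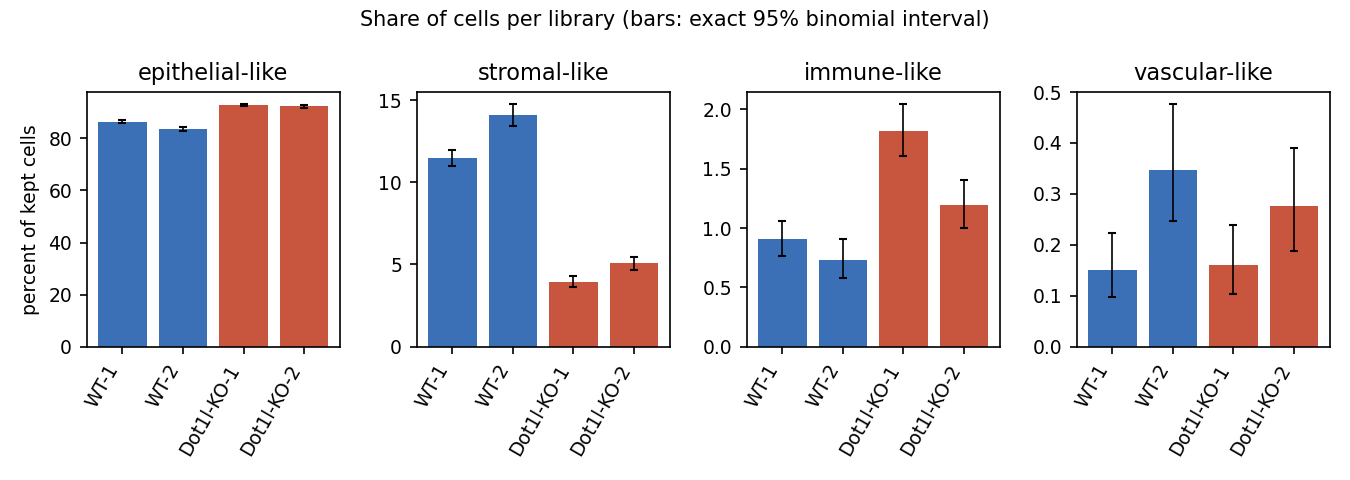
Share of cells per class in each library, in percent of kept cells, as bars from 0 with exact 95% binomial intervals, each class on its own scale. Stromal-like cells were between 11.45% and 14.09% in WT and between 3.95% and 5.06% in Dot1l-KO.

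The share of epithelial-like cells with a UMI of chosen genes was read at equal depth, after thinning to 1500 UMIs, which left out 281 WT and 184 Dot1l-KO cells. Cells with Krt14 made up 32.3% ± 1.26 in WT and 81.6% ± 5.66 in Dot1l-KO (SD, n = 2; exact permutation p = 0.333), where stromal-like cells gave 2.86% and 19.0% as background. For Krt12 the shares were 86.7% ± 6.385 and 63.65% ± 3.58, against a background of 45.7% and 22.5%, so this background differed between the genotypes as well, by library 57.5% and 33.8% in WT and 28.2% and 16.8% in Dot1l-KO. Pax6 was seen in 36.0% ± 1.455 and 23.8% ± 3.63 of cells (background 1.56% and 0.962%). Mki67 was seen in 2.39% ± 0.301 and 4.89% ± 0.1825 (background 0.146% and 0.265%) and Top2a in 3.04% ± 0.0908 and 6.07% ± 0.301 (0.525% and 0.789%). Krt5 (97.0% and 97.1%), Krt15 (57.2% and 58.8%) and Trp63 (13.6% and 14.8%) overlapped between the genotypes, with backgrounds of 22.4% and 17.0%, 15.5% and 8.60%, and 0.639% and 0.876%. Dot1l was seen in 3.43% and 3.15% of epithelial-like cells and 3.21% and 4.75% of stromal-like cells, which left out 53 and 19 cells.

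Unthinned, the shares of epithelial-like cells with a UMI in WT and Dot1l-KO were 98.2% and 87.4% for Krt12, 49.5% and 94.9% for Krt14, 99.6% and 99.5% for Krt5, 80.1% and 82.4% for Krt15, and 83.1% and 74.2% for Pax6, which overlapped between the genotypes. They were 46.3% and 54.0% for Trp63, 7.02% and 16.7% for Mki67, 7.22% and 15.5% for Top2a and 17.5% and 19.3% for Dot1l. The unthinned background in stromal-like cells was 82.0% and 53.4% for Krt12, 8.97% and 42.8% for Krt14, 4.78% and 2.94% for Pax6, 0.497% and 0.779% for Mki67, and 1.21% and 1.73% for Top2a. Unthinned, epithelial-like cells had median depths of 8163, 10814, 9399 and 11172 UMIs by library, and stromal-like cells 4341, 5661, 4588 and 5911.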

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

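The 2 tests of the Krt14 pattern and the fits without cluster 12 were chosen after the result was seen. The change between genotypes differed between basal-like and suprabasal-like cells by an edgeR genotype by class test, which picked the genes here. Krt14 rose by 0.78 on the log2 scale in basal-like and by 6.45 in suprabasal-like cells, a difference of 5.60 ± 0.13 (SE; adjusted p = 1.54e-08). Among keratin genes the difference was 3.76 for Krt4, 1.97 for Krt13, 1.54 for Krt10, 0.69 for Krt6a and 0.64 for Krt15. Without cluster 12, whose conjunctival score was above its basal score and which made up 20.8% of WT and 8.22% of Dot1l-KO basal-like cells, the differences were 5.585 for Krt14, 3.42 for Krt4, 1.37 for Krt13 and 1.405 for Krt10. That of Krt15 then ended (-0.19, adjusted p = 0.355) and that of Krt6a reversed (-0.745, 0.0133). There were 76 genes called in both layers with opposite signs, but without cluster 12 only 29 of these, and 14 of the 53 that were lower in basal-like cells. Those outside the fixed lists and with large differences were the sphingolipid synthesis gene Sptssb (-0.74 and 4.19, difference 4.93), the uridine phosphorylase gene Upp1 (-1.21 and 1.125, 2.32) and Lgi2 (-0.79 and 1.49, 2.28). From the lists came the simple-epithelium keratin gene Krt19 (-0.78 and 2.90, 3.65), the interleukin antagonist gene Il1rn (-0.99 and 1.84, 2.81) and the tight junction gene Cldn1 (-0.59 and 1.98, 2.56). Without cluster 12 the basal-like falls of Sptssb (-0.61, adjusted p = 0.2615), Upp1 (-0.37, 0.437), Lgi2 (-0.12, 0.790) and Cldn1 (-0.56, 0.0987) were no longer called, and Krt19 turned to 0.40 (0.321). The falls of Sptssb and Cldn1 kept most of their size, while those of Upp1, Lgi2 and Krt19 did not. The basal-like fall of Il1rn stayed called (-0.69, 0.0371). The difference between layers stayed past the threshold for these 6 genes, at 4.75, 1.46, 1.59, 2.52, 2.42 and 2.49 in that order. The Krt13 call in suprabasal-like cells ended without WT replicate 1 (0.29) and without WT replicate 2 (0.51).

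Krt14 in suprabasal-like Dot1l-KO cells was weighed against a naming error and against free RNA. Cluster 8 lay at the boundary to basal-like cells, but outside it the lowest Krt14 level of a Dot1l-KO suprabasal-like cluster was 14.7 times the highest of a WT one (1284 against 87.3 CPM), which argues against misnamed basal cells in that cluster as the whole cause. Krt14 in Dot1l-KO stromal-like cells was 3.91% of its level in suprabasal-like cells, which argues against free RNA. These values are consistent with Krt14 being kept on in cells that carry suprabasal markers, as a hypothesis. Whether these cells match WT suprabasal cells in other ways stays open, since nearly all cells of these clusters came from a single genotype.

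Cluster 25, left unnamed, entered the sums over all cells but no comparison of a class. It held 266 cells with a median of 2066 UMIs and 10.6% mitochondrial UMIs, and no marker led its genes. It made up 0.194% ± 0.0356 of WT and 0.802% ± 0.166 of Dot1l-KO cells (SD, n = 2), 4.13-fold more, and its source was not tested. The other unnamed clusters, 26, 30 and 31, went the other way, at 0.473, 0.409 and 0.0947 times the WT share. Cluster 31 came nearly all from WT replicate 1.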

How the results depend on the processing

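The counts without scaling factors, without epithelial-high genes, without cluster 12 and with fry in either direction were chosen after the data were examined, and so were the conjunctival-like and cycling comparisons. Outside the summary results, 12825 recomputed values were rated the same, most of them of named genes. Those of named genes kept their direction and their side of the threshold. Among values of named genes 723 lost their call, 17 gained one and 22 reversed. The 6 values that moved were not of named genes. Of the summary results 169 were rated the same, 39 moved and 5 reversed. With 2 libraries per genotype a fit without a library assumes that the lone library varies like the other genotype. Depth limited immune-like cells, with 80 to 271 cells per library. Where no cause is given, the cause was not tested.

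Without scaling factors, which shifts all log2 changes up, the changes in epithelial-like cells of Trp63 (0.15), Krt4 (0.23) and Krt13 (0.013), of Dot1l in stromal-like cells (0.033) and of Dot1l (0.29), Trp63 (0.16) and Krt10 (0.14) in conjunctival-like cells reversed. Without cluster 12 Krt6a in basal-like cells (0.77) reversed. With doublets kept Krt6a in basal-like cells (0.39) and Retnlg in immune-like cells (-0.0074) reversed. With classes from resolution 0.5, Krt13 (-0.073) and Krt6a (-0.29) in suprabasal-like cells reversed. After library-centred clustering Krt13 (-0.41) and Krt6a (-0.045) in suprabasal-like and Lamb3 in conjunctival-like cells (-0.020) did. Thinning reversed Dot1l in stromal-like (0.42) and conjunctival-like cells (0.24). Leaving out each library gave -0.062 to 0.095 for Krt6a in suprabasal-like cells, -0.18 to 0.039 for Dot1l in stromal-like and -0.32 to 0.083 for Dot1l in conjunctival-like cells. Krt6a reversed without WT replicate 1 and Dot1l-KO replicate 1, and Dot1l without WT replicate 2 and Dot1l-KO replicate 2 in stromal-like and without Dot1l-KO replicate 1 in conjunctival-like cells. None of the Dot1l values were called.

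A 2-fold minimum, which can only lower counts, left 3227 genes in all cells, 3595 in epithelial-like, 1949 in basal-like, 3588 in suprabasal-like and 476 in stromal-like cells, and all 86 in immune-like cells. With at least 10 CPM in 2 libraries, 2679, 3000, 1742 and 2643 genes passed in all, epithelial-like, basal-like and suprabasal-like cells, where this tests fewer genes. In immune-like cells, where it tests more (8778 against 7098), 52 passed. Thinned, 4022, 4745, 1955 and 3003 passed in the same classes, 265 in stromal-like and 12 in immune-like cells. With classes from resolution 0.5, 5765 passed in basal-like cells. The DESeq2 Wald test called 542 in stromal-like and 53 in immune-like cells. In immune-like cells 354 passed with no filter on low counts, 149 with doublets kept and 44 with stricter cells.

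Leaving out each library gave 4950 to 6019 genes in all cells, 5425 to 7525 in epithelial-like, 2626 to 3460 in basal-like, 4504 to 7853 in suprabasal-like, 625 to 1460 in stromal-like and 51 to 293 in immune-like cells, 2933 to 3567 with a different change between layers, and 13 to 14 lists. The labels do not say whether libraries with the same replicate number shared a day or batch, so a shared batch stays open. Correlations of the same-number differences were 0.231, 0.170, 0.153, 0.1301, 0.195 and 0.113 in the 6 classes in that order, and with replicate number as a block 8148, 8310, 4694, 8482, 2996 and 54 genes passed.

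By camera with an estimated correlation 0 lists passed, against 30 by fry in either direction. Shares with a UMI changed in points by -10.9 for Krt12, -8.91 for Pax6, 7.77 for Trp63, 9.67 for Mki67 and 8.26 for Top2a unthinned, where the genotypes overlapped for Pax6 and Trp63, and by -15.6 for Pax6, 4.77 for Mki67 and 4.70 for Top2a at 3000 UMIs. The differences for Krt5 (-0.0757 with stricter cells, -0.0921 unthinned) and Dot1l (1.79 unthinned, 0.0264 at 3000 UMIs) and the vascular-like share (0.0045 with stricter cells) reversed.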

Other observations

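The test of diluted corneal cells was set before its result was seen. The other tests of Krt12 and those of the interferon genes were chosen afterwards, and the comparisons of conjunctival-like and cycling epithelial-like cells were added after the data were examined. In conjunctival-like cells (clusters 20, of mostly WT cells, 7, of mostly Dot1l-KO cells, and 21) Isg15 fell from 1149 ± 125 to 83.2 ± 23.02 CPM (SD, n = 2; 13.8-fold lower, edgeR adjusted p = 7.87e-06). Krt15, higher here in WT than in the other classes tested, fell from 18510 ± 1455 to 9542 ± 786 CPM (1.94-fold lower), and Krt14 rose from 1207 ± 219.7 to 2062 ± 634 CPM (1.71-fold), a call that the DESeq2 Wald test did not make (adjusted p = 0.1425). The mucosal keratins Krt4 (log2 -0.86) and Krt13 (-0.96) fell. Krt12 fell from 1349.5 ± 438 to 304 ± 116 CPM (log2 -2.15, -2.74 with doublets kept and -1.32 after library-centred clustering). Cluster 20 held 567 CPM of Krt12, near the 543 CPM of the stromal-like cluster 1. Cluster 21 held 1693 CPM and made up 33.1% of WT and 13.7% of Dot1l-KO conjunctival-like cells. Free RNA and class makeup were not separated from expression for this fall. Gabrp, a receptor channel gene, rose from 1.31 ± 0.832 to 48.8 ± 23.8 CPM (log2 5.155, 6.06 without WT replicate 2, 4.54 without Dot1l-KO replicate 2 and 6.69 thinned). Dot1l did not pass (log2 -0.10, adjusted p = 0.691; 0.08 without Dot1l-KO replicate 1). Of interferon response genes 1 rose and 23 fell of 25 (1 and 23), with counts adjusted over the list alone in parentheses, of antigen presentation genes 0 rose and 16 fell of 17 (0 and 16), of mitochondrially encoded genes 11 rose and 0 fell of 13 (12 and 0) and of oxidative phosphorylation genes 0 rose and 10 fell of 28 (0 and 10). In all, 4103 of 12891 genes passed, 2157 higher and 1946 lower. The median moved to 0.40 without scaling factors and 6012 genes passed, 2825 of them among these 4103, so the balance of higher and lower depends on scaling.

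In cycling epithelial-like cells (clusters 14, of mostly Dot1l-KO cells, 16 and 17) Krt12 fell from 10500 ± 3459 to 3736 ± 299 CPM (SD, n = 2; log2 -1.49, edgeR adjusted p = 0.00199) and Krt14 rose from 2433 ± 72.4 to 5361 ± 1877 CPM (2.20-fold). Cluster 17, with 15485 CPM of Krt12, made up 57.9% of the WT and 18.15% of the Dot1l-KO cells of this class. Cluster 14, with 3342 CPM of Krt12 and 6820 CPM of Krt14, made up 0.886% and 52.6%. Class makeup and expression thus mix in these values. The wound keratin gene Krt6a rose from 743 ± 45.5 to 1553 ± 421 CPM (2.09-fold) and S100a8 from 5.18 ± 0.984 to 784 ± 331 CPM (153-fold). Isg15 fell from 118 ± 12.7 to 14 ± 4.27 CPM (8.41-fold lower) and Ifi27l2a, another interferon-induced gene, from 1078 ± 61.3 to 125 ± 13.0 CPM (8.60-fold lower). Of S phase genes 0 rose and 0 fell of 41 (0 and 0), with counts adjusted over the list alone in parentheses, so that edgeR called 0 of these, with 1 higher and 1 lower at an unadjusted p under 0.05. Of G2 and M phase genes 0 rose and 1 fell of 52 (0 and 0), of keratinization genes 16 rose and 2 fell of 24 (17 and 2) and of interferon response genes 1 rose and 19 fell of 25 (1 and 22). The class was named by a score over cell cycle markers, most of them on the G2 and M phase list. Cells of both genotypes were thus chosen to be alike in such genes, so the few calls in the cell cycle lists may follow from the naming. Dot1l did not pass (log2 -0.53, adjusted p = 0.126), but did without Dot1l-KO replicate 2 (-0.72, 0.0210). In all, 1684 of 13732 genes passed, 1049 higher and 635 lower. The median moved to 0.07 without scaling factors and 1611 genes passed, 1484 of them among these 1684. The genotypes did not overlap in 68.3% of conjunctival-like and 53.5% of cycling genes tested, where chance gives 33.3%.

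Lower Krt12 in the epithelium was weighed against scaling and against dilution. Without scaling factors the log2 change of Krt12 was still -1.65, which argues against scaling as the whole cause. If cells lacking Krt12 had diluted unchanged corneal cells, 15.8% and 14.5% of cells in Dot1l-KO replicates 1 and 2 would lie above the WT median of 30 Krt12 UMIs at equal depth. The shares were 10.9% and 8.87%, below this but above the bound set in advance, so dilution and lower Krt12 per cell cannot be told apart by this test. The median cell had 2 Krt12 UMIs in either Dot1l-KO library.

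Lower interferon response genes were weighed against free RNA, against a single library and against differences between the pools of mice. The 10 members that fell in stromal-like cells stood there in WT at a median of 32.4% of their epithelial level, where corneal markers stood at 3.099%, which argues against free epithelial RNA as the source in stromal-like cells, with Isg15 as an exception within 3 times the marker ratio. All 24 members lower in epithelial-like cells stayed called with any library left out, which argues against a single library. The same 24 members had both WT libraries above both Dot1l-KO libraries, but pool and genotype go together, so housing, infection or handling of the pools cannot be told apart from the genotype. A lower interferon tone without Dot1l may be proposed as a hypothesis, untested against these. Free epithelial RNA was not tested as a source of the falls in immune-like cells.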
